A study of Drosophila melanogaster with 6 samples.

How the data were processed

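Total RNA from whole adult Drosophila melanogaster, kept for 7 days on standard food per the labels' protocols, was hybridised to Affymetrix arrays. The labels name 3 arrays of the wild-type strain Canton S and 3 arrays of the DHR96 mutant, and the series' design text calls the controls genetically matched. DHR96 is the older name of Hr96, a nuclear receptor. The biotin-labelled cRNA was made from 6 ug of total RNA per the labels. Nothing in the labels says whether the 3 samples of a group came from separate collections of animals, so the p-values measure only the spread between these samples, which may be technical.

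The deposited values are linear probe set intensities that the authors had already normalized between arrays, as their nearly coinciding quantiles show. The submitters' processing notes name MAS5, with no version or role. The nearly coinciding quantiles and the lack of values near 0 leave unsettled whether these values are MAS5 signals, so their background correction and summary method are not known here. The array medians lay between 470.4 and 484.2, and the lowest value of each array between 97.2 and 103.4, so the background was not taken to 0 and the folds of dim probe sets may be too small. Detection calls were not used here. The number of arrays limits the precision.

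A deposited table of the authors' own comparison holds 286 rows for 260 probe sets. Per the file headers it gives a SAM score, its numerator on the log2 scale, its denominator, a signed fold and a q-value in percent; the authors' listed folds were all at least 1.301 in size and the q-values at most 2.181%. The numerator in the deposited table equalled the mean log2 value of the mutant arrays minus that of the Canton S arrays within 5.68e-10 for every row, which settles its direction. The source of its gene ontology terms is not given in the sources used here.

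Of 18952 probe sets, 183 manufacturer's controls were set aside and 18769 were tested with no filter on low values. limma 3.58.1 in R 4.3.3 was fitted to log2(intensity + 16) with the group as the only term, with lmFit and then eBayes with an intensity trend. Tests were two-sided with Benjamini-Hochberg adjustment over the 18769 probe sets and a threshold of 0.05. Fold changes are on the log2(intensity + 16) scale, and log2 differences are mutant minus Canton S throughout. On simulated data with 200 changed probe sets among 18769, the procedure recovered 76% of those changed 1.3-fold, 88% at 1.5-fold, 98% at 2-fold and 100% at 4-fold, with 10 false calls of 191 and 0 calls in the wrong direction. The simulated noise was normal and independent between probe sets, with no batch, so these rates may not hold for the real arrays.

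No table pairing all probe sets of the array with genes was used here, so genes were named only from the authors' deposited table, through their CG numbers and the gene table of Release 6 of the fly genome. Of the 260 probe sets, 251 matched and 9 did not and kept the file's name. Among the 260, 3 name several genes and stay unnamed, and 6 genes have a pair of probe sets, which leaves 251 genes, each represented by its brightest probe set. The build behind the files is not given in the sources used here, and no coordinates are reported; the gene table served for names and gene order alone. For the genes with more than 1 listed probe set, the probe sets had the same direction and were all past the threshold.

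A competitive gene set test (camera) over 24 gene lists had been planned before the data were examined, as had the lists, the fit, the alternatives and the rule for naming genes. It needs the names of all probe sets and was not run. In its place, the members of each list in the deposited table were counted. For lists of at least 5 such genes, Fisher's exact test (two-sided, SciPy 1.17.1) compared their directions with those of the other named genes. Counts adjusted over the list alone were not computed for the same reason. Together with the ontology terms of the deposited table, chosen after the data were seen, this made 42 tests adjusted as one family. Terms that hold the same genes each count as a test. The authors chose their table on these same arrays, so counts within it are not independent evidence of direction.

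Genes were named by this rule: Hr96; the 12 largest rises and 12 largest falls past the threshold whose group values did not overlap; and in each fixed list up to 4 members past the threshold, or the member of smallest p where none passed. It named 47 genes, and others are said to be chosen after their values were seen. Alternatives were another scaling, other pseudocounts, a filter on dim probe sets, other variance models and thresholds, Welch's statistic, the replicate number as a block and each array left out in turn. A block for labelling batch and a fit with no pseudocount were added after seeing the data. The batch was inferred from the poly-A spike-in controls, which separate 2 arrays labelled DHR96 mutant from the other 4, and not from any label. The overall profiles do not group these 2 arrays, DHR96 mutant replicates 2 and 3. Their log2 values correlated at 0.9939 (Pearson), against 0.9952 for replicates 1 and 2 and 0.9973 for replicates 1 and 3. DHR96 mutant replicate 1 correlated at 0.9954 with Canton S replicate 2.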

Results

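The data are intensities of 18769 probe sets on 6 arrays of whole adult flies, 3 from the strain Canton S and 3 labelled DHR96 mutant. The comparison asks which transcripts differ in level between animals mutant for this nuclear receptor and their controls. The ratios of 3' to 5' control probe sets, a sign of RNA quality, averaged 2.32 in Canton S and 2.46 in the arrays labelled DHR96 mutant for actin, 1.32 and 1.38 for GAPDH, and 2.37 and 2.46 for eIF-4a. DHR96 mutant replicate 2 had the highest of each (2.61, 1.42 and 2.70), while replicate 3 read 2.31, 1.36 and 2.27.

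The targeted gene Hr96 (CG11783) did not fall. Its probe set read 527, 498 and 546 on the Canton S arrays and 977, 985 and 928 on the arrays labelled DHR96 mutant, or 524 ± 24.2 against 963 ± 30.7 (SD, n = 3 each). The difference was 0.86 on the log2 scale (SE 0.0486, limma adjusted p = 0.000195), higher in all 3 mutant arrays. The labels do not give the mutation or the position of the probe set relative to it, so this value does not check the labels, and the direction of every difference rests on them.

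Of the named genes, Npc2e had the largest rise and Npc2d, LManV, LManVI and mag the largest falls. Npc2e (CG31410), of a family of sterol-binding proteins, rose 20.7-fold in the arrays labelled DHR96 mutant, from 567 ± 43.3 to 12017 ± 546 (SD, n = 3 each; SE 0.0585 on the log2 scale; limma adjusted p = 5.96e-08). Its family member Npc2d (CG12813) fell 11.8-fold, from 2412 ± 314 to 189 ± 17.0 (SE 0.0977, limma adjusted p = 4.57e-06). The lipase gene mag (magro, CG5932) fell 4.005-fold, from 5481 ± 436 to 1354 ± 19.8 (SE 0.0568, limma adjusted p = 4.57e-06). The lysosomal alpha-mannosidase genes LManV, LManVI and LManIII fell 5.82-fold, 4.29-fold and 3.18-fold.

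In all, 1306 probe sets passed the threshold, 617 higher and 689 lower in the arrays labelled DHR96 mutant, with a median fold of 1.183. That balance depends on some of the processing choices: higher calls made up 47.2% here, 57.6% (630 higher, 463 lower) after quantile normalization and 56.9% to 64.1% with an array left out. They stayed a minority at 47.9% after median centring, 46.9% with robust variances and 42.6% with the dimmest probe sets left out. Of the 1306, 258 changed at least 1.3-fold (174 higher, 84 lower) and 31 at least 2-fold (19 higher, 12 lower). The 3 values of a group did not overlap those of the other for 5792 probe sets, or 30.86%, against 10% by chance, and these included all 1306. The authors' deposited table lists 180 probe sets as higher and 80 as lower, of which 167 and 76 passed limma. The remaining 1063 past the threshold carry no name here. By gene, the table names 171 as higher and 80 as lower, and 235 of the 251 passed. Left out in turn, Canton S replicates 1, 2 and 3 gave totals of 287, 803 and 494 probe sets, and DHR96 mutant replicates 1, 2 and 3 gave 450, 587 and 426. The poly-A spike-in controls set DHR96 mutant replicates 2 and 3 apart: the Dap 3' control read 473 and 519 there, against 1217 in replicate 1 and 1188, 1208 and 1007 in Canton S. With that inferred batch as a block, which leaves DHR96 mutant replicate 1 against the 3 Canton S arrays, the differences of the 235 named genes were a median 0.893 of those without the block. All 235 had the same direction, but this was fixed in advance, since their groups did not overlap. Their selection on these same arrays also favours a high ratio.

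**Figure D1:**
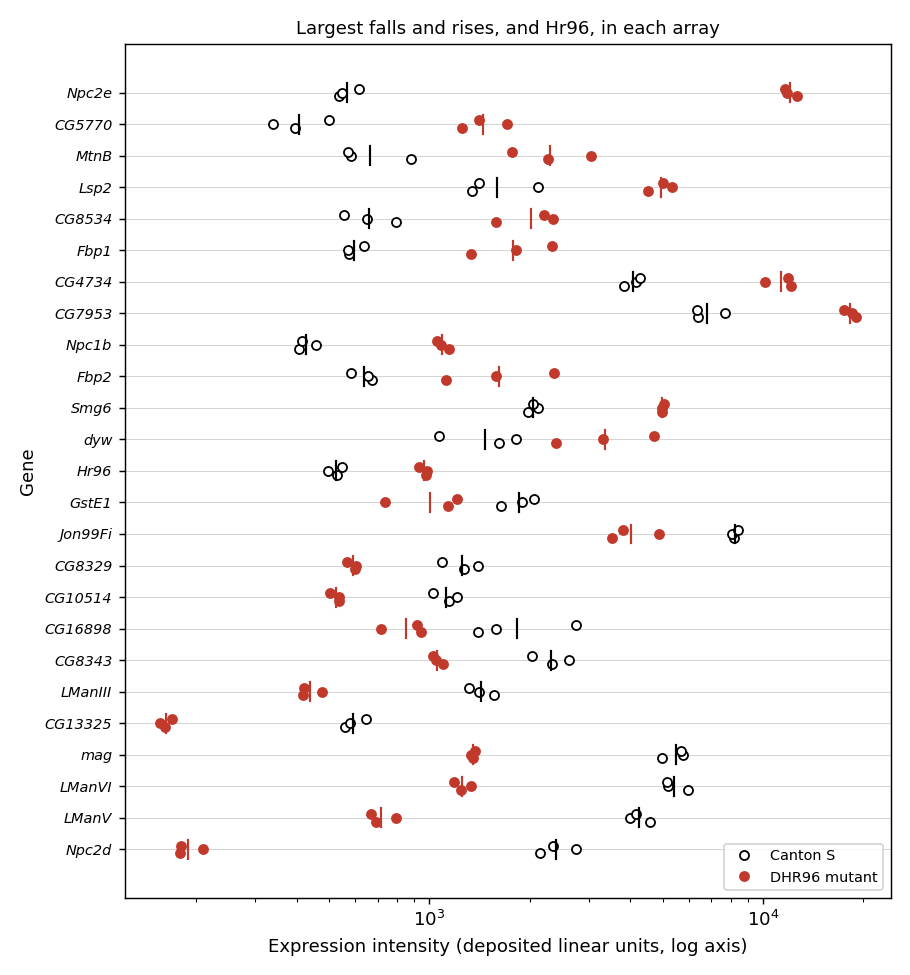
Intensity of Hr96 and of the 12 genes with the largest rise and the 12 with the largest fall, on a log axis in the authors' deposited linear units. Open circles are the 3 Canton S arrays, filled circles the 3 arrays labelled DHR96 mutant, and vertical bars the geometric group means. Groups that do not overlap were a condition for all genes shown but Hr96, whose groups did not overlap either. The arithmetic mean of Npc2e ran from 567 to 12017.

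Genes of the sterol transport and lipoprotein list moved both ways. Of 7 genes of this list in the deposited table, 2 rose and 4 fell. Npc1b, a gene for sterol uptake in the midgut, rose from 426 ± 26.4 to 1094 ± 49.4 (SD, n = 3 each; log2 difference 1.33, SE 0.0570, limma adjusted p = 4.19e-05), beside Npc2e. Npc2h fell by 0.47, and Npc2g and the scavenger receptor gene ninaD, both named after their values were seen, fell by 0.48 and 0.54 on the log2 scale, beside Npc2d. Npc2c, likewise named afterwards, read 262 ± 11.2 in Canton S and 446 ± 129 in the arrays labelled DHR96 mutant, with a limma adjusted p of 0.05001, just over the threshold. A difference in direction from the other named genes was not detected (Fisher's exact p = 0.214, 0.449 adjusted over 42 tests). With the labelling batch as a block, Npc2e, Npc1b and Npc2d passed.

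All 3 lipase genes in the deposited table fell: mag, CG31091 by 0.85 and sxe2 by 0.63 on the log2 scale (limma adjusted p = 0.00201 and 0.00126). The group was too small for the test of direction. In the batch-blocked fit, CG31091 did not pass (log2 difference -0.88, limma adjusted p = 0.0661).

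The group of lysosomal alpha-mannosidase genes was taken from the ontology terms after the data were seen. All 5 in the deposited table fell, LManV from 4248 ± 311 to 717 ± 65.9 (SD, n = 3 each; log2 difference -2.54, SE 0.0747, limma adjusted p = 4.79e-06). LManVI and LManIII fell by 2.10 and 1.67 on the log2 scale, and LManII and LManI, outside the naming rule, by 0.87 and 0.39. None of the 5 was higher, against 171 of the other 246 named genes (Fisher's exact p = 0.00301, 0.0422 adjusted over 42 tests). The same 5 genes were tested again under a mannose metabolism term, and both tests count among the 42. Passing after adjustment rests on that repeat. The authors selected these genes on the same arrays. With the labelling batch as a block, 4 of the 5 passed.

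Of 6 midgut serine protease genes in the deposited table, 5 fell and 1 rose. Jon99Fi, of the Jonah digestive proteases, fell from 8214 ± 164 to 4067 ± 715 (SD, n = 3 each; log2 difference -1.03, SE 0.106, limma adjusted p = 0.00393). Jon99Ci fell by 0.62 and iotaTry by 0.67, while Ser8 rose by 0.72 on the log2 scale. Jon65Ai and Jon65Aii, named after their values were seen, had log2 differences of -0.79 and -0.77. With the labelling batch as a block, Jon99Fi, Jon99Ci and iotaTry differed by -1.22, -0.53 and -0.71, and Jon65Ai, Jon65Aii and Ser8 by -0.92, -0.90 and 0.71. The group's Fisher's exact p was 0.0135, or 0.0849 adjusted over 42 tests and 0.0540 over the 4 fixed lists tested, which does not pass. The ontology term for serine-type endopeptidases, chosen afterwards and holding 4 of the same Jonah genes with CG3088, had 5 of 5 lower (Fisher's exact p = 0.00301, 0.0422 adjusted). That adjusted p passes only because the repeated test of the mannosidase genes counts in the family. Without DHR96 mutant replicate 1, 3 of the 6 fixed members passed; with the labelling batch as a block, Jon99Fi and Jon99Ci did.

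Detoxification genes were mixed. Of 5 cytochrome P450 genes, 3 fell and 2 rose: Cyp6g1, known for insecticide resistance, fell by 0.59, Cyp6t1 by 0.45 and Cyp4aa1 by 0.40, and Cyp4s3 rose by 0.47 and Cyp4e3, named after its value was seen, by 0.89 on the log2 scale (Fisher's exact p = 0.331, 0.496 adjusted). Of 3 genes of the glutathione S-transferase list, which holds only genes with a Gst symbol, GstE1 and GstE3 fell by 0.87 and 0.60 on the log2 scale (limma adjusted p = 0.0322 and 0.0173). GstE7, named afterwards, had a log2 difference of -1.05 with a limma adjusted p of 0.0535. Leaving out Canton S replicate 3 left 0 of the glutathione S-transferase genes past the threshold, Canton S replicate 1 or 2 or DHR96 mutant replicate 1 left 1, and the labelling batch as a block left 0 genes of either family by limma's adjusted p, with 5 P450 and 2 glutathione S-transferase genes at an unadjusted p under 0.05.

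Of 6 genes of the fat body list in the deposited table, 5 rose, none fell and 1 did not pass: Lsp2, a larval serum protein, from 1624 ± 425 to 4970 ± 410 (SD, n = 3 each; log2 difference 1.63, SE 0.158, limma adjusted p = 0.00307), Fbp1 and Fbp2 by 1.56 and 1.32, the odorant-binding protein gene Obp99b by 0.79, and Lsp1gamma, named after its value was seen, by 1.07 on the log2 scale. Lsp1beta, also named afterwards, read 1228 ± 81.6 and 1930 ± 476 (limma adjusted p = 0.0514). A difference in direction from the other named genes was not detected either (Fisher's exact p = 0.181, 0.449 adjusted). The number past the threshold was 2 without Canton S replicate 1 or 3, 3 without Canton S replicate 2, and 0 with the labelling batch as a block, where 5 had an unadjusted limma p under 0.05. The log2 differences were then smaller: 1.503 for Lsp2, 1.15 for Fbp1, 0.81 for Fbp2, 0.68 for Lsp1gamma and 0.61 for Obp99b.

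Genes with a chitin, cuticle or peritrophic term, a group formed after the data were seen, were mostly higher. Of 23 in the deposited table, 20 rose, 2 fell and 1 did not pass. Members chosen after their values were seen include Cht5, a chitinase gene, from 1290 ± 248 to 2950 ± 760 (SD, n = 3 each; log2 difference 1.17, limma adjusted p = 0.0209), the chitin synthase gene kkv, up by 0.82, and the cuticle protein gene Cpr62Bc, up by 0.89 on the log2 scale. Cht9 and CG33173 fell by 0.53 and 0.45. The share higher, against the other named genes, had a Fisher's exact p of 0.01004, or 0.0849 adjusted over 42 tests, which does not pass. Without Canton S replicate 1, 13 of the 23 passed, and with the labelling batch as a block 0 did by limma's adjusted p and all 23 had an unadjusted p under 0.05, with the difference of Cht5 at 0.73.

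Of 4 antimicrobial genes in the deposited table, a group too small for the test of direction, 3 rose and 1 fell, against 168 higher and 79 lower among the other named genes. PGRP-SC2 rose by 0.71, AttC by 1.16 and Drs (drosomycin) by 0.50, while Drsl5 fell by 0.51 on the log2 scale. PGRP-SC2, which encodes a peptidoglycan recognition protein, went from 3093 ± 106 to 5080 ± 203 (SD, n = 3 each; SE 0.0412, limma adjusted p = 0.000219) and was the 1 of the 4 that passed with the labelling batch as a block. Among 3 carbohydrase genes, Mal-B1 and tobi, which encode alpha-glucosidases, rose by 0.56 and 0.48, and Mal-B2 fell by 0.64 on the log2 scale. The glycogen branching enzyme gene AGBE rose by 0.42 and the accessory gland gene Acp76A by 0.43, each the 1 gene of its list in the deposited table; tobi was the 1 gene of the insulin and starvation list. The circadian list held takeout (to), which fell by 0.53. With the labelling batch as a block, tobi, Mal-B1 and Mal-B2 differed by 0.66, 0.395 and -0.46, and AGBE, Acp76A and takeout by 0.37, 0.35 and -0.47. None of these carbohydrase, AGBE, Acp76A and takeout differences passed with the labelling batch as a block.

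The deposited table held 0 genes of the other 12 fixed lists: lipid synthesis and storage, beta-oxidation, UDP-glycosyltransferases, stress, eggshell and yolk, germline, testis, eye, neuron, muscle, Malpighian tubule and ribosomal proteins. That shows only that none met the authors' selection, since their probe sets are not identified by name here.

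Among the other large rises, the metallothionein gene MtnB went from 677 ± 174 to 2362 ± 639 (SD, n = 3 each; log2 difference 1.77, SE 0.218, limma adjusted p = 0.00714) and CG5770 from 411 ± 80.5 to 1459 ± 230 (1.79, SE 0.149, limma adjusted p = 0.00160). CG8534, CG4734, CG7953 and dyw rose by 1.59, 1.47, 1.43 and 1.18 on the log2 scale. With the labelling batch as a block, the differences of MtnB, CG5770 and CG8534 were 1.75, 1.59 and 1.24. Smg6, a gene of nonsense-mediated mRNA decay, rose from 2045 ± 75.2 to 4988 ± 37.9 (1.28, SE 0.0350, limma adjusted p = 4.57e-06). Of the other large falls, CG13325 went from 592 ± 45.4 to 162 ± 6.86 (-1.77, SE 0.0637, limma adjusted p = 1.58e-05), a mutant level under the 184 at which the median of 99 control probe sets stood in Canton S. So near the background the falls of CG13325 and of Npc2d may be understated. CG8343, CG16898, CG10514 and CG8329 fell by 1.12, 1.09, 1.07 and 1.06 (-1.06, -0.94, -1.05 and -1.04 with the labelling batch as a block). Of these genes, CG4734, CG7953, Smg6, CG13325 and CG10514 passed with the labelling batch as a block, and the difference of dyw was then 0.71.

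**Figure D2:**
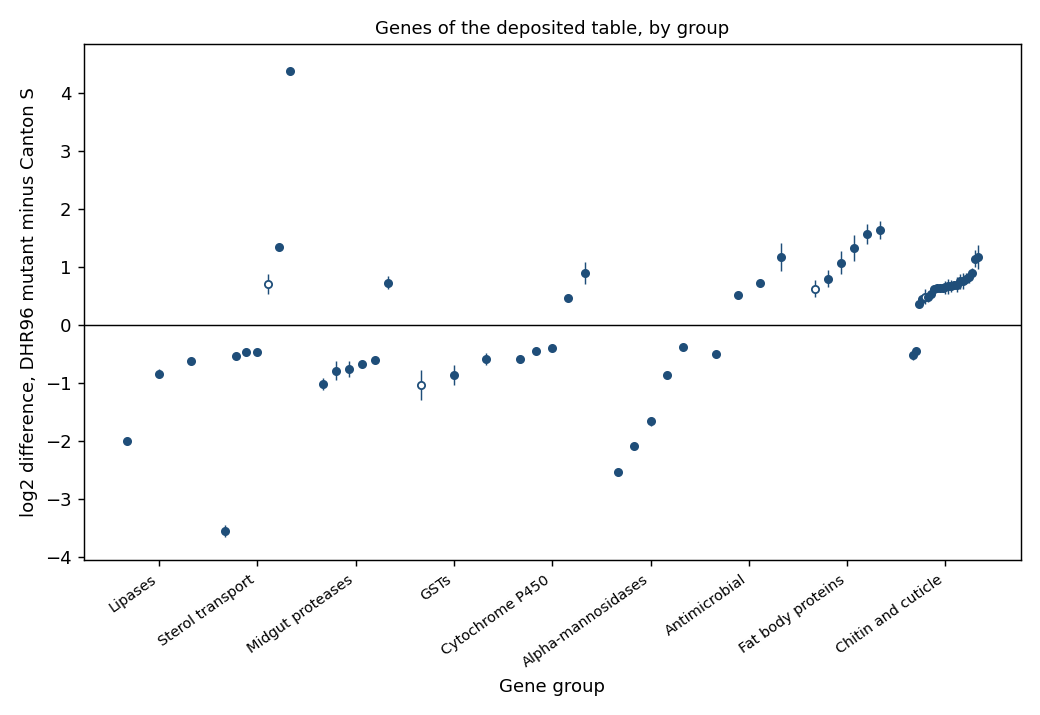
Log2 difference in intensity, DHR96 mutant minus Canton S, of the deposited table's genes by group; each point is a gene, bars are its standard error from limma, filled points passed the threshold and open points did not. All 5 alpha-mannosidase genes and all 3 lipase genes lie below 0, and the 6 fat body genes lie above it.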

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

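The tests in this part were chosen after the results they bear on had been seen, except the count of splits of the arrays. The real split gave 1306 probe sets past the threshold and 1 of the 10 splits of the 6 arrays into 3 and 3 gave as many, the real one; the highest of the other splits gave 0 with limma, and those splits had 203 to 902 probe sets at an unadjusted p under 0.05, against 4581. With 10 splits no share under 0.05 can be reached.

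Among the manufacturer's 183 control probe sets, which take no part in the comparison, 2 passed the threshold, adjusted over the controls, and both were higher in the arrays labelled DHR96 mutant than in Canton S. Of 3 controls for the 3' end of GAPDH, 1 differed by 0.34 on the log2 scale (1933 ± 137 against 2455 ± 65.9, SD, n = 3 each; limma adjusted p = 0.0228 over the controls), while the other two differed by 0.034 and 0.069 (limma adjusted p = 0.697 for each). The other control past the threshold, whose identifier was not matched to a sequence here, read 468 ± 38.0 in Canton S and 21711 ± 136 in the arrays labelled DHR96 mutant (SD, n = 3 each), a log2 difference of 5.49, with all 3 mutant arrays between 21556 and 21811.

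That control was weighed together with Hr96 and the genes on either side of it in gene order, EMC6 and Smg6, of which EMC6 was chosen after its value was seen (1016 ± 46.8 to 2081 ± 42.1, SD, n = 3 each) and all rose. The labelling batch is argued against, since within it the smallest of the 4 log2 differences was 0.88, over 3 of its standard errors, with 1 mutant array against 3. So is a larger amount of hybridisation control on the mutant arrays, since the 18 bacterial and phage controls had a median log2 difference of 0.0289, from -0.088 to 0.105. A wide segment differing between the strains stays open, since 3 named genes lay among the 50 genes to each side beyond EMC6 and Smg6, against 1.94 by chance (permutation p = 0.304). Sequence introduced with the mutation may underlie the control's difference of 5.49 and also stays open, because its sequence was not identified here and the labels do not describe the allele, and the 468 in Canton S, with 4 of the 99 other controls of its series as high, does not settle whether the sequence was absent there. The highest of those 4 averaged 25008 in Canton S and tracked the phage controls across arrays, so it does not bear on the background.

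Npc2e rose and its neighbour Npc2d fell. Signal passing between their probe sets would move both the same way, and the -3.56 of Npc2d against the 4.37 of Npc2e argues against it as the cause. Within the labelling batch Npc2d differed by -3.63 and Npc2e by 4.44, so the batch is also argued against. A sequence difference between the strains that ends probe binding stays open for Npc2d, which lay at or below the 13.4 percentile of probe sets in the arrays labelled DHR96 mutant, where 53 of the same 99 controls read as low, as they also would with no transcript. It likewise stays open for Npc2e, which lay at the 54.1 percentile or higher in Canton S, where 3 of those controls read as high. The highest of these controls averaged 25008 and tracked the phage controls across arrays, so it does not stand for an unbound probe set. The level of Npc2e is thus unusual for an unbound probe set, which does not rule that out. A change in the genes' own expression is a further hypothesis that these arrays do not separate from a sequence difference.

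Lsp2, Lsp1beta, Lsp1gamma, Fbp1 and Fbp2 and the 21 higher genes of the chitin and cuticle group, a set picked for being higher and without Obp99b, had a median log2 difference of 0.67, and 24 of the 26 passed. Another scaling of the arrays is argued against, since the smaller of the medians under quantile normalization and median centring was 0.66. The labelling batch stays open: DHR96 mutant replicate 1 lay 0.62 above the Canton S mean, where the Canton S arrays had an SD of 0.126, but within the batch none of the 26 passed limma's adjusted p. The median difference there was 0.54 with a median standard error of 0.136, in place of 0.67 and 0.110, and a smaller difference, fewer arrays and the adjustment were not told apart as reasons. A difference in age or stage between the collected animals may also contribute and stays open, though the labels give 7 days for both groups. The serum and cuticle genes rank the 3 mutant arrays alike, up to a serum gene mean of 1.61 in replicate 3. Any cause shared by these genes could do so, and 3 arrays are too few to decide. A response to the mutation itself was not tested.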

How the results depend on the processing

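Hr96 kept its direction and passed in all limma fits run (other scalings, pseudocounts, variance models, dim filter, blocks and arrays left out); at 1.81-fold it is under the 2-fold requirement. None of the 251 named genes turned direction in these fits (245 were fitted with the dimmest probe sets left out). The groups of the 235 genes past the threshold did not overlap, so for them only the other scalings could have turned a direction. The total of 1306 probe sets became 240 with the replicate number as a block, 813 without the intensity trend, 2 with Welch's statistic, 2522 at adjusted p under 0.1, and 258 or 31 with a fold of at least 1.3 or 2 also required; the labelling batch as a block, added after seeing the data like the fit with no pseudocount, gave 31, and leaving out each array gave 287 to 803. The 235 named genes past the threshold became 148 with the replicate block and 29 with the labelling batch, and 159 to 210 with an array left out. Leaving out an array leaves fewer samples; the cause of the other shifts was not tested, and lost samples were not separated from a batch effect in the labelling block. A pairing of the samples by replicate number is not evident, though so few values cannot exclude it: deviations of same-numbered arrays correlated at 0.190, -0.225 and -0.244 across probe sets. The replicate block left 0 glutathione S-transferase, 3 P450, 3 fat body, 4 midgut protease and 8 chitin or cuticle genes past the threshold. The share of higher calls, 47.2%, turned to a majority at 57.6% after quantile normalization, 58.7% without the trend, 55.8% with the replicate block and 56.9% to 64.1% with an array left out. It stayed a minority at 47.9% after median centring, 47.3% with the other pseudocounts and 46.9% with robust variances. With the dimmest probe sets left out it was 42.6%, and at adjusted p under 0.1 it was 44.8%. Requiring a fold of at least 1.3 or 2 gave 67.4% or 61.3%. Of 46 genes named by the rule besides Hr96, 30 no longer passed with the labelling batch, 10 with the replicate block, 6 with robust variances, 2 without the trend and 4 to 9 with an array left out; with the dimmest probe sets left out, 1 was not tested and 45 passed, and all 46 passed under the other scalings and pseudocounts. For gene lists, camera, its estimated correlation, fry, the other choice of probe set and every other setting of that test were not run. Intensities not reduced to background limit the folds of dim probe sets such as Npc2d.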

Other observations

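The genes in this part were chosen after their values were seen. The ecdysone-induced transcription factor gene Eip74EF rose in the arrays labelled DHR96 mutant, from 669 ± 7.26 to 908 ± 81.3 (SD, n = 3 each; log2 difference 0.43, limma adjusted p = 0.0132). The 4 proteasome subunit genes in the authors' deposited table, Rpn2, Rpn3, Rpn11 and Rpt3, rose by 0.38 to 0.41 on the log2 scale, and their direction was not tested as a group. The odorant-binding protein genes Obp56e, Obp83cd and Obp83g rose by 0.56, 0.54 and 0.49. The prophenoloxidase gene PPO1 fell from 553 ± 14.9 to 390 ± 3.70 (SD, n = 3 each; log2 difference -0.49, limma adjusted p = 0.00196). With the labelling batch as a block, PPO1 differed by -0.50, and Obp56e, Obp83cd and Obp83g by 0.49, 0.47 and 0.44. The proteasome genes then differed by 0.26 to 0.30. None of these genes passed with the labelling batch as a block, where Eip74EF differed by 0.28.

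Named genes lay next to each other more often than randomly placed genes. Of 245 placed in the order of the 13951 protein-coding genes, 26 pairs were adjacent, against a mean of 4.27 and a highest of 13 in 10000 random placements, and 20 of the 26 pairs shared a direction, against a mean of 14.8 when the directions were shuffled among the placed genes (permutation p = 0.0252, one-sided, chosen after the pairs were seen). Several pairs are members of one gene family, such as LManV and LManVI, Npc2g and Npc2h, and Jon65Ai and Jon65Aii. EMC6 with Hr96 and Hr96 with Smg6 are also among the pairs that shared a direction. The shuffle treats family members as independent. The random placements drew on all protein-coding genes, whether or not the array reads them. Npc2e, Npc2d and Npc2c are consecutive, with log2 differences of 4.37, -3.56 and 0.70. Mal-B1 and Mal-B2 are adjacent and differed by 0.56 and -0.64. Of the probe sets past the threshold outside the deposited table, 22 changed at least 1.3-fold and 1 at least 2-fold; this unnamed probe set fell from 1002 ± 94.7 to 394 ± 51.2 (SD, n = 3 each; log2 difference -1.32, limma adjusted p = 0.00117).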
